A study of Mus musculus with 7 samples.

How the data were processed

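The data come from RNA immunoprecipitation sequencing (RIP-seq) in CT26.WT, a mouse colon cancer cell line. In this assay an antibody pulls a protein out of a cell extract together with the RNA it holds, and that RNA is sequenced. The antibody here was against HuR, the RNA-binding protein encoded by Elavl1. The labels describe 7 samples: 3 HuR immunoprecipitations, 3 immunoprecipitations with control IgG and 1 input of total RNA. Nothing in the labels says whether the 3 immunoprecipitations came from separate cultures, and the series describes the input as a shared RNA sample.

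Per the submitters' processing notes, reads passed through FastQC, cutadapt 1.9.3, STAR and HISAT2 2.0.4, and the genome build was mm39; the notes as used here give no role or order for these tools. The site names in the files carry the prefix of the MACS peak caller; its version, its settings and the library used as control are not given in the sources used here. Sites were called per sample, and the deposited tables are a list for each of the 3 HuR immunoprecipitations, a joined list and 11 gene symbols without values. Each list holds part of the calls, because the highest site number was 35258, 37141 and 39806 while 4722, 5384 and 7966 sites are listed. The joined list of 15392 sites was checked against the others: it holds all of list 1, then the sites of list 2 that overlap no site of list 1 (818 left out), then the sites of list 3 that overlap neither (1862 left out). It was used for counts of sites per gene, for the genes annotated with fat digestion and absorption, for the search for sites on chromosomes M or Y and for this check. The IgG and input libraries were not analysed here, and read depth per library is unknown.

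Per the file headers, the fold enrichment of a site is the caller's ratio of signal over control. The score, per the file headers, is minus 10 times the log10 of the caller's p, and the lowest score corresponds to a p of 1e-05. The FDR is read here as percent; it is the authors' deposited value, and the reading as percent comes from its range. All folds, scores and FDRs per site are the authors' values, and they were used only to describe, rank or filter sites within a list. They carry no replicate error. Site ends were taken as half-open intervals and are printed with the start counted from 1, on mm39.

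Sites of different lists were called shared when they overlapped by at least 1 base, and a merged region counted for all 3 lists when it held a site of each. A preset placement of sites at random within genes needed gene bounds on mm39, which were not used here. It was replaced, after the data were examined, by moving lists 2 and 3 as a whole in opposite directions by 2000 to 20000 bases, 100 times. An earlier form of this control let both lists move together, which left real overlaps in place, and was corrected. Because such moves can carry sites off exons, a low count of shared regions follows from the control itself, and it is not used as a measure of agreement. Genes are named as the files name them. Naming by the gene identifiers in the files was tried at the start and dropped because it misnamed Plin2; with the files' names, 10 in place of 9 members of the fat absorption list had a site. Of the names, 6249 were found in a RefSeq gene table of the GRCm38 assembly and 28 were not; this table served only for names and for the number of protein-coding genes, 21900, because its build differs from that of the files. The wide background used for some tests holds these genes and the 47 listed genes that the table does not give as protein-coding, 21947 in all.

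Gene lists were fixed before the data were examined: triglyceride synthesis, intestinal fat absorption, sterol and fatty acid synthesis, lipolysis and fatty acid oxidation, reported HuR targets, immediate early genes and cytokines, RNA-binding stability factors, cell cycle, abundant housekeeping genes, epithelial and mesenchymal markers, other cell types, ribosomal protein genes and replication-dependent histone genes. A list of mitochondrially encoded genes had no usable member and was dropped; the histone list was defined by a symbol pattern and also took in linker histone genes that are not replication-dependent, such as H1f0 and H1f10; no site lay on chromosomes M or Y. The reported HuR targets were written from general knowledge of the literature. Each list was tested with Fisher's exact test, two-sided, for genes with a site in all 3 lists against genes with a site in any, with Benjamini-Hochberg adjustment over the 13 lists and a threshold of 0.05. Log2 odds ratios have 0.5 added to each cell. Genes are not replicates, so these p-values say nothing about the spread between immunoprecipitations. Intervals of shares are exact binomial 95% intervals and cover counting error only. Named genes were chosen by a rule fixed before the data were examined: the 10 genes with the highest fold, taken as the lowest over the 3 lists of each gene's best site, unnamed gene models left out; every member of the triglyceride synthesis and fat absorption lists with a site in all 3 lists; Dgat1, Dgat2, Mogat2, Agpat4, Fabp2, Cd36, Mttp and Apob always; Elavl1 and up to 6 reported HuR targets by highest fold; and from each other list the 2 members with the highest fold and a member without a site. Any other gene named was chosen after its values were seen.

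The planned tests of HuR against IgG and against input need a value per library and were not made, because the lists hold called sites. The planned shares of sites in untranslated regions, coding exons and introns, the U content of the sites and a model with gene length need an mm39 sequence or annotation and were not run. Tests of single immunoprecipitations (39 tests), of KEGG pathways as the files annotate them (231 terms of at least 10 genes) and of genes with any site against the wide background were added after the data were examined. Pathways were also tested for the genes of each immunoprecipitation in turn, where 0 of 231 passed after adjustment and 13, 9 and 20 had an unadjusted p under 0.05 in lists 1, 2 and 3 (Fisher's exact test). The overlap code was tested on simulated data, where it found 200 of 200 planted shared regions among 18072 sites. The gene list test was run 200 times on simulated lists of 20 among 6277 genes: a list planted with 4-fold odds was called in 53.5% of runs and an unplanted list in 0.125%. The tested lists had 1 to 20 members among these genes, with 15 for triglyceride synthesis and 10 for fat absorption. The 53.5% therefore does not give the power for the smaller lists. The work used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Alternatives were stricter fold and p thresholds, stricter overlap, lists of equal length, leaving out each immunoprecipitation in turn, another background and a site in at least 2 lists.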

Results

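HuR was immunoprecipitated from CT26.WT mouse colon cancer cells to find the mRNAs it holds, in a study concerned with triglyceride synthesis and the uptake of fat by the intestine. The data analysed were the sites called by the authors in each of 3 HuR immunoprecipitations, with a fold enrichment over a control that is not named in the sources used here. Libraries of 3 IgG immunoprecipitations and 1 input belong to the same series. They were not analysed here, so no test below compares HuR with IgG or with input. Whether the unnamed control behind the folds was IgG or input is not known. Read depth is unknown. Each site value comes from a single library and has no replicate error.

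The HuR immunoprecipitations gave 4722, 5384 and 7966 sites in 3423, 3625 and 3942 genes. The median fold enrichment was 7.21 in list 1, 6.41 in list 2 and 8.38 in list 3, and the median site length was 176, 161 and 152 bases. The joined list held 20 sites in Mycbp2, a ubiquitin ligase gene, and 19 each in Lrrk2, Syne1 and Vps13b, counts that are not adjusted for gene length. These genes were singled out after their counts were seen. The highest fold of list 1 was 46.5 at Col1a1 (chromosome 11, 94842299 to 94843868, mm39), a collagen gene, which had no site in the other lists. The highest fold of list 2 was 253 at Trim30a and that of list 3 was 64.9 at H2-Q2; both genes belong to families of near-identical copies, so the source of their reads is uncertain. The caller's FDR was 38.96% at the Col1a1 site, 39.35% at Trim30a and 25.09% at H2-Q2. The values of Col1a1 and Trim30a equalled the highest FDR of their lists. Requiring a caller p at or under a hundredth of the largest left 3184 sites in list 1, 3372 in list 2 and 5225 in list 3. The caller's median FDR was 15.5% in list 1, 13% in list 2 and 9.73% in list 3, and 1 site in all had an FDR under 5%, in list 3 at Eno1b, a near-identical copy of Eno1 whose reads cannot be assigned with certainty.

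The lists were then compared to ask how far the immunoprecipitations found the same sites. A site of another list was overlapped by 29.8% of the sites in list 1 (95% interval 28.5 to 31.1%), 35.4% in list 2 (34.1 to 36.7%) and 23.4% in list 3 (22.5 to 24.3%). Regions with a site in all 3 lists numbered 195; how many would be shared by chance among the exons of the same genes was not tested. Among them were a region of Agpat2 on chromosome 2 (26487216 to 26487349), with folds of 5.64, 4.54 and 10.8, and a region of Scarb1 on chromosome 5 (125366701 to 125366819), with folds of 3.36, 3.31 and 7.23. Where sites of lists 1 and 2 overlapped, 67.8% shared the same start and end, and for lists 1 and 3 and lists 2 and 3 the share was 74.7% and 81%. At the stricter caller p, 66 regions were shared by all 3 lists. Counts for any pair were higher, as a pair asks less: 814 regions without list 3, 779 without list 2 and 1276 without list 1.

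**Figure D1:**
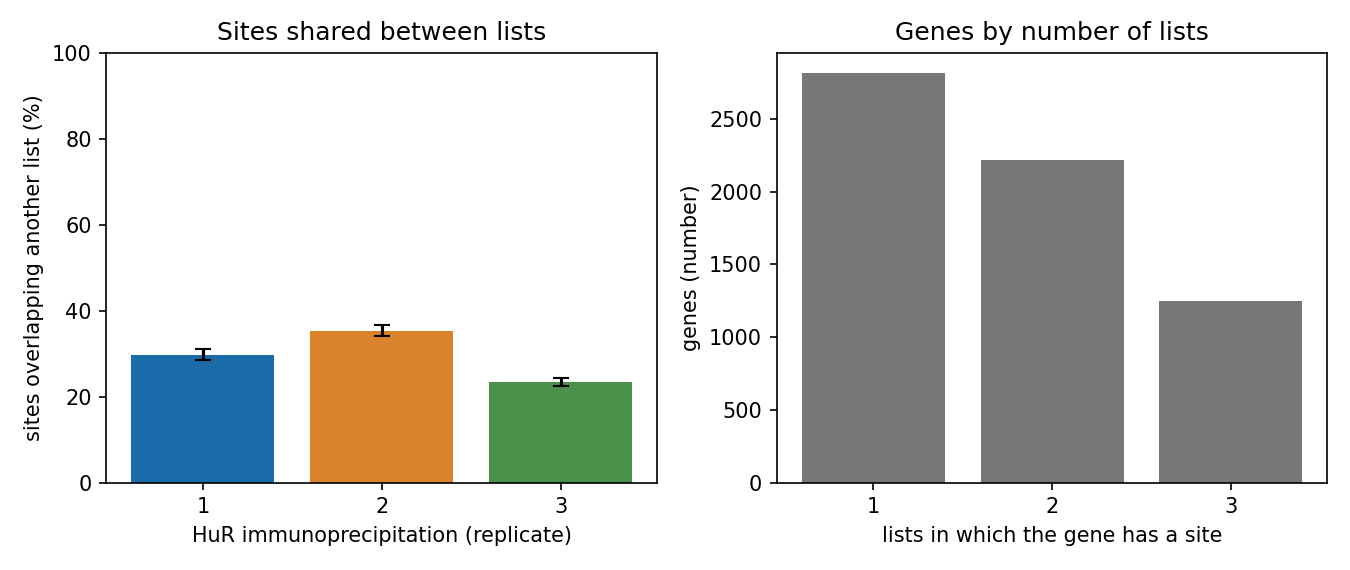
Left, the percentage of sites in each HuR immunoprecipitation that overlap a site of another list by at least 1 base, with exact binomial 95% intervals; the bars stand at 29.8, 35.4 and 23.4%. Right, the number of genes with a site in exactly 1 list (2812), exactly 2 lists (2217) and all 3 lists (1248).

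The lists were compared by gene as well. A site was listed in 6277 genes in all, and 1248 of them (19.9%) had a site in every list, against 102 expected if the lists were independent over 21900 protein-coding genes, a figure that takes no account of which genes the cells express. Of the 1248 genes, 191 (15.3%) had a region shared by all 3 lists. Of the genes common to a pair of lists, 42% had an overlapping site in lists 1 and 2, 36.7% in lists 1 and 3 and 49% in lists 2 and 3. The 10 named genes whose lowest best fold over the 3 lists was highest were Rps6ka2, Lrch2, Inpp4a, Ggcx, Copg2, Nol10, Atm, Senp5, Ids and Usp28. Some of their folds recur exactly, as 11.48 for Atm and Senp5 in list 1 and 12.41 for Atm and Copg2 in list 2. How many reads each fold rests on is unknown, so this ranking need not follow the strength of binding. Rps6ka2, which encodes a ribosomal S6 kinase, had best folds of 15.1, 14 and 14.5. Its region shared by all 3 lists on chromosome 17 (7437514 to 7437842) had folds of 10.6, 14 and 8.81. The best sites of lists 1 and 3 lay elsewhere in the gene. Inpp4a, a phosphoinositide phosphatase gene, had best folds of 12.9, 16 and 16.4 on chromosome 1; the best sites of lists 1 and 3 overlapped (37447630 to 37448165), and that of list 2 lay at 37448709 to 37449502. Ggcx, which encodes the vitamin K-dependent carboxylase, reached 12.4, 14.2 and 13.2, and Atm, the DNA damage kinase gene, reached 11.5, 12.4 and 12.4, each with no region common to all lists. Usp28, a deubiquitinase gene, had a region shared by all 3 lists on chromosome 9 (48938119 to 48938189) with folds of 16.5, 8.41 and 9.21. The best folds in lists 1, 2 and 3 were 12.9, 14 and 13.5 for Lrch2, 16.7, 12.4 and 11.6 for Copg2, and 15.6, 12.8 and 11.6 for Nol10. They were 11.5, 12.35 and 18.3 for Senp5 and 11.5, 15.6 and 15.9 for Ids. The stricter caller p left 600 genes in all 3 lists. Without list 1 there were 2243 genes in the other two and without list 2 there were 1902.

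The question of the series turns on lipid genes, and the list of triglyceride synthesis enzymes was taken up next. Of its 21 genes, 15 had a site in at least 1 list and 5 had a site in all 3: Lpin1, Agpat2, Acsl4, Gpat3 and Acsl3. Among these 5, Agpat2 alone had a region common to all 3 lists. Lpin1, which encodes a phosphatidate phosphatase, had best folds of 9.33, 7.61 and 11.6. Gpat3, a glycerol-3-phosphate acyltransferase gene, had 7.9, 8.81 and 9.61. The acyltransferase gene Agpat2 had 5.64, 5.97 and 10.8, and the fatty acid activating genes Acsl4 and Acsl3 had 9.64, 5.15 and 10.1 and 7.36, 5.18 and 8.09. The only Lpin1 site of list 2 had a score of 63.5, and the only Gpat3 site of list 1 had 69.7. Both lay under the score of 70 that the stricter caller p requires, so neither gene stays in all lists there. The test of gene lists for genes in all lists was not run at that setting. Agpat4 had a site at the same position in lists 1 and 2 (chromosome 17, 12435581 to 12435779), with folds of 5.51 and 6.41, and none in list 3. Dgat2, which encodes an enzyme of the last step of triglyceride synthesis, had 1 site, in list 1, with a fold of 7.81, and Dgat1 and Mogat2 had no listed site. The same fold recurred in list 1 at Aldoa and H1f10, and the score of the Dgat2 site, 67.3, was also under 70. Against all genes with a site, of which 19.9% were in every list, the 5 of 15 members (33.3%) were not distinguishable (Fisher's exact test, two-sided, p = 0.197, adjusted p = 0.578, log2 odds 1.08). Against the wide background of 21947 protein-coding and listed genes, whether expressed or not, 23.8% of the 21 members compared with 5.69% (exact test, log2 odds 2.47, adjusted p = 0.0363).

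For fat absorption, 10 of 27 genes had a site and 2 had a site in all lists. Abca1, which encodes a cholesterol exporter, had best folds of 8.44, 6.41 and 12.7, and Scarb1, which encodes a lipoprotein receptor, had 3.36, 5.39 and 7.23. Abca1 had no region common to all lists, whereas Scarb1 had the shared region given above. Mttp, needed to load lipid onto apolipoprotein B, had sites in list 1 (fold 9.18) and list 2 (fold 6.3) at different positions. Fabp2, Cd36 and Apob had no listed site. The share of members in all lists, 20%, lay beside the 19.9% of all genes with a site (exact test, adjusted p = 1). The authors' deposited table of 11 gene symbols held 3 genes with a site in all lists (Scarb1, Abca1 and Agpat2), 3 in exactly 2 and 5 in exactly 1. All 9 genes that the files annotate with fat digestion and absorption are among those 11; the symbols are the authors' choice and are not independent evidence.

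**Figure D2:**
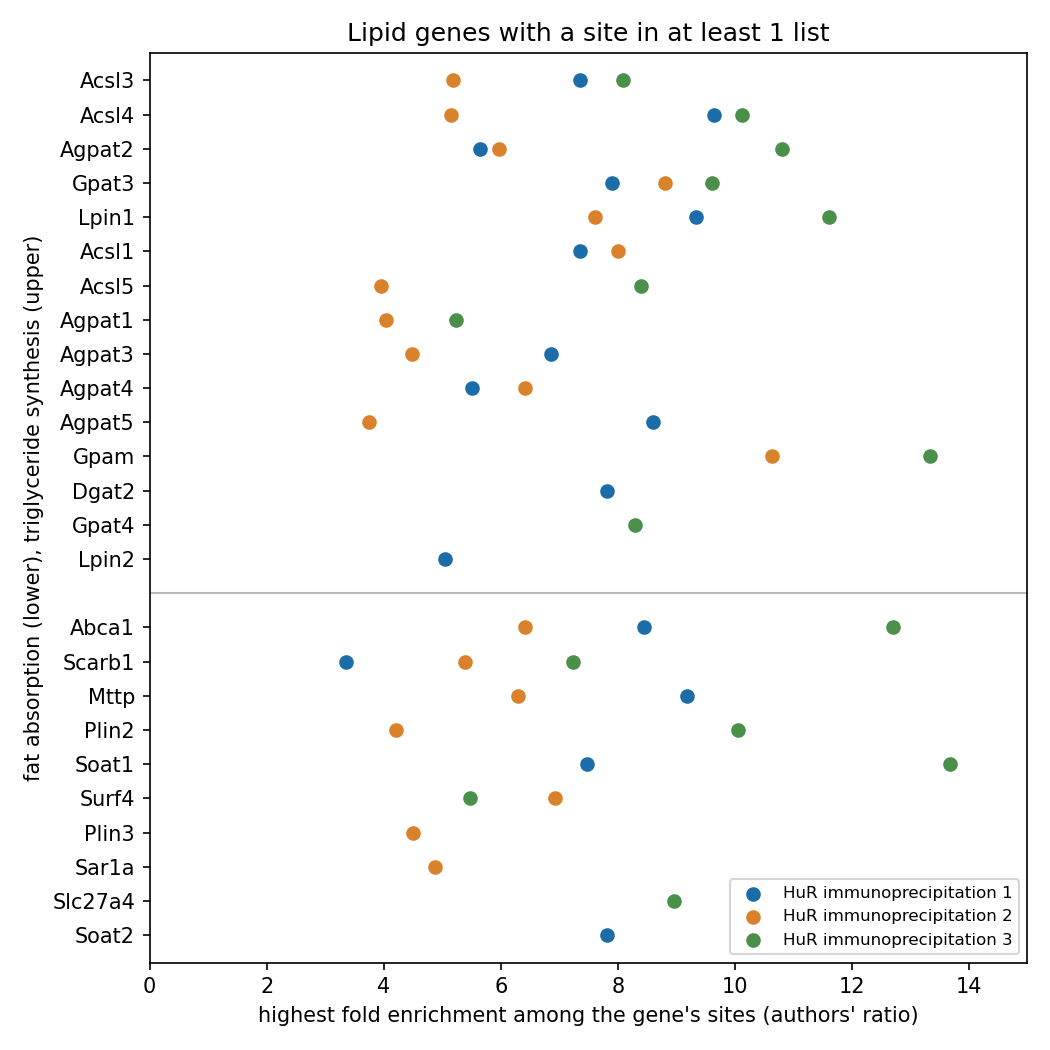
Highest fold enrichment, as the authors' ratio of signal over control, among the sites of each lipid gene with at least 1 listed site; each point is a gene in 1 HuR immunoprecipitation, and a missing point means no listed site. Lpin1 has points at 9.33, 7.61 and 11.6, whereas Dgat2 has a single point at 7.81.

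Genes for RNA-binding stability factors had the largest share of members in all lists, 7 of 17 (41.2%), which did not pass the test (exact test, p = 0.0593, adjusted p = 0.578, log2 odds 1.53). Elavl1, Msi2, Igf2bp2 and Zfp36l2 were among them. The mRNA of HuR itself, Elavl1, had best folds of 9.63, 5.16 and 10.9, with sites of lists 2 and 3 at the same position on chromosome 8 (4354927 to 4355030). Msi2, a translational regulator, had 5.35, 7.64 and 11.8, and Elavl2 had no listed site. Against the wide background, 24.1% of 29 members compared with 5.69% (exact test, log2 odds 2.47, adjusted p = 0.0127). Of the reported HuR targets 16 of 30 had a site and 1, Elavl1, was in all lists. Hmgb1 had a site in list 1 alone (fold 15.3), Xiap in lists 1 and 3 (13.8 and 5.56), Mdm2 in lists 2 and 3 (4.08 and 13.7), Ptma in lists 1 and 2 (11.1 and 8.86), and Tlr4 and Plaur in list 3 (9.72 and 9.16). In list 1 the caller's FDR was 38.96% at the Ptma site, equal to the highest of that list, and 20.08% at Hmgb1. The share of the reported HuR targets in all lists, 6.25% against 19.9%, did not pass the exact test (adjusted p = 0.578).

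The remaining lists did not pass either. Lipolysis and fatty acid oxidation had 4 of 10 genes in all lists, among them Abhd5, a lipase co-activator gene, with best folds of 8.96, 8.82 and 14.4, and Hadh, a beta-oxidation gene, with 6.92, 4.68 and 11.9 at a shared region on chromosome 3 (131034586 to 131034658); Pnpla2 had no site. Sterol and fatty acid synthesis had 2 of 11, Srebf2 reached 13.4 in list 2 and Sqle 11.4 in list 3, and Fasn had no site. Cell cycle genes had 3 of 20, among them Cdk6 (11.5, 7.32 and 13.9) and E2f3 (9.95, 6.05 and 15), and Ccnd1 had no site. Immediate early genes and cytokines had 1 of 8, with Fosb at 9.18 and 10 in lists 1 and 2, Csf1 at 5.31 and 7.97 in lists 2 and 3, and Fos without a site. Abundant housekeeping genes had 2 of 6, including Eno1 (7.89, 6.2 and 8.17), with Aldoa at 7.81 in list 1 and Gapdh without a site. The caller's FDR at these Eno1 sites was 30.15, 19.05 and 10.61%, and reads of Eno1 and its copy Eno1b cannot be assigned with certainty. Epithelial and mesenchymal markers had 0 of 9, with Zeb1 at 9.21 and 9.95 in lists 2 and 3 and Epcam without a site. Ribosomal protein genes had 0 of 1, Rpl21 being the listed gene (4.96 and 5.39 in lists 1 and 2) and Rpl10 a gene without a site, and histone genes had 0 of 2, H1f10 (7.81) and H3c1 (3.73), both in list 1, with H1f0 without a site; H1f10 and H1f0 are replication-independent linker histone genes that the list also took in. Markers of other cell types had 0 of 2, Alb (16) and Hbb-bs (15.5), both in list 2, and Ptprc had no site. By Fisher's exact test 0 of 13 lists passed after adjustment and 0 had an unadjusted p under 0.05; against the wide background 2 passed and 4 had an unadjusted p under 0.05.

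**Figure D3:**
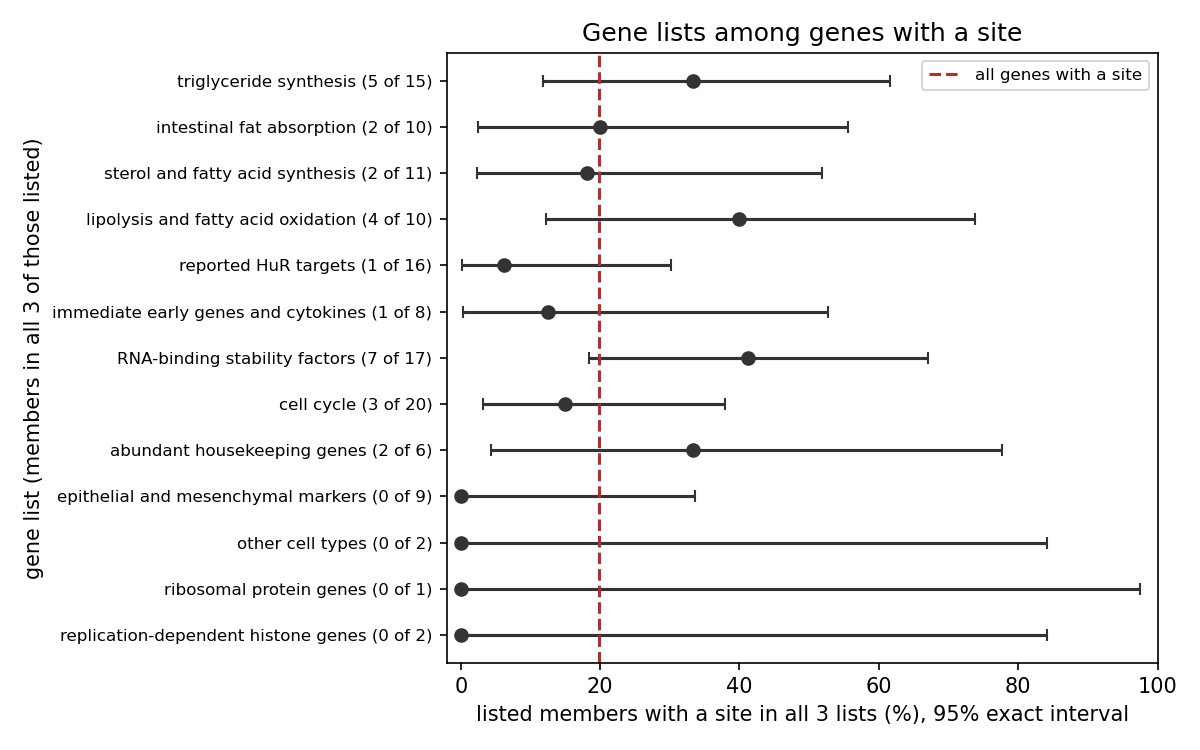
Percentage of each list's genes with a site that have a site in all 3 HuR immunoprecipitations, with exact binomial 95% intervals; the dashed line marks 19.9%, the share of all 6277 genes with a site. RNA-binding stability factors (41.2%) and lipolysis and fatty acid oxidation (40%) stand highest, and every interval includes the dashed line.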

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

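The FDR setting, the tests of single immunoprecipitations and the tests of genes with any site were chosen after the data were seen. No paired analysis was possible because the lists hold called sites and no value per library for HuR and IgG. The counts of sites, shared regions and shared genes stayed within 1.5 times at a fold of at least 4.34. A caller p at or under a hundredth of the largest left 3184 sites in list 1, 3372 in list 2 and 5225 in list 3. It left 66 regions in all lists and 600 genes in all lists, which follows from fewer sites being compared. Stricter overlap kept the number of shared regions within 1.5 times of 195. With each list cut to its 4722 highest-scoring sites, the length of the shortest list, 883 genes had a site in all lists, against 1248. Leaving out each immunoprecipitation in turn gave 779 to 1276 shared regions and 1816 to 2243 shared genes, as a pair of lists asks less than 3. An FDR at or under each list's median left 412 genes in all lists; because the FDR rose with the score in list 3 and fell with it in lists 1 and 2, this kept mostly low-scoring sites of list 3 and is not a stricter setting. For gene lists, 0 passed with a site in at least 2 lists, with the stricter fold, and without each immunoprecipitation. With the wide background of protein-coding and listed genes 2 passed, triglyceride synthesis and RNA-binding stability factors; that background also holds genes the cells do not express, and how much this contributes was not tested. Among the genes of list 1 alone 1 list passed, cell cycle, lower with 4 of 20 members (exact test, adjusted p = 0.0328 over 13 lists and 0.0985 over all 39 tests of single immunoprecipitations; 3 of the 39 had an unadjusted p under 0.05); the cause was not tested. A change of sign between log2 odds that both missed the threshold was not counted. Tests of HuR against IgG and input, site location, U content and the model with gene length were not run. Unknown depth and lists that hold part of the calls limit every statement that a gene has no site or that a site is not shared.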

Other observations

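Of the tests in this part, those of genes with any site, of pathways, of overlap by score and of a library listed more than once were chosen after the results they concern were seen.

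When all genes with a site in any list were set against the wide background of 21947 protein-coding and listed genes, of which 28.6% had a site, 6 of 13 lists passed and 7 had an unadjusted p under 0.05 (Fisher's exact test, two-sided, adjusted over the 13 lists). Higher shares were found for triglyceride synthesis (15 of 21, exact test, adjusted p = 0.000253), cell cycle (20 of 32, adjusted p = 0.000286), RNA-binding stability factors (17 of 29, adjusted p = 0.00196) and reported HuR targets (16 of 30, adjusted p = 0.00932). Members with a site in lists 1, 2 and 3 numbered 11, 12 and 9 for triglyceride synthesis, 12, 13 and 12 for RNA-binding stability factors, 4, 14 and 15 for cell cycle and 4, 10 and 11 for reported HuR targets. The higher share of cell cycle genes does not come from list 1, which held 4 of the 20 with any site (20%) and 54.5% of all genes with a site; this difference did not pass over the 39 tests of single immunoprecipitations (exact test, log2 odds -2.14, p = 0.00253, adjusted p = 0.0985). Lower shares were found for ribosomal protein genes (1 of 83, exact test, adjusted p = 6.34e-10) and histone genes (2 of 65, adjusted p = 1.53e-06), a list that also holds replication-independent members such as H1f10 and H1f0. The reported HuR targets no longer passed without immunoprecipitation 2 (exact test, adjusted p = 0.0687) or 3 (adjusted p = 0.111). The background holds genes that the cells do not express, gene length was not taken into account, and the lists of reported targets, cell cycle and RNA-binding factors have members in common, such as Elavl1 and Ccna2. Among the KEGG pathways annotated in the files, 0 of 231 passed for genes in all lists and 7 had an unadjusted p under 0.05; mTOR signaling had the smallest p (14 of 35 genes, exact test, p = 0.0105, adjusted p = 1).

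Few sites overlapped between lists although many genes did. A candidate explanation is that the sites lie near the caller's threshold. The 25% of sites with the highest score did not overlap other lists much more often than the lowest 25%: the difference was -3.45 percentage points in list 1, 0.0743 in list 2 and 2.78 in list 3, and the highest upper 95% bound was 5.37 points. Neighbouring pieces of the same mRNA region stay open: 0.644% of the sites without an overlap lay within 200 bases of a site of another list, but pieces in adjacent exons lie an intron apart, and 66.5, 72.8 and 74.4% of these sites in lists 1, 2 and 3 lay in a gene of another list. Each list holds part of the calls, so a site without an overlap may still have been called, but not listed, in another immunoprecipitation. Sampling of few reads per site stays open too, as read counts were not analysed, and no biological explanation was tested.

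Overlapping sites often shared both bounds. Sites that were limited to annotated exons may explain this, because coding exons are a multiple of 3 bases long more often than chance. Among 1900 sites with the same bounds in at least 2 lists, 38.8% had such a length (95% interval 36.6 to 41%), above the bound of 36% set before the test; among the other 14132 sites the share was 36.7% (35.9 to 37.5%). At most 23.8% of the shorter list overlapped the other in any pair, so no list was a copy of another. This share was known before the question of a library listed more than once was put, and each list holds part of the calls. It therefore cannot decide whether the same library was called more than once. No exon annotation of the build was used, and no biological explanation was tested.

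List 2 held sites in albumin (Alb, fold 16) and in the haemoglobin genes Hbb-bs (15.5) and Hbb-bt (32), and list 1 held a site in Hbb-bt (11). RNA of blood or liver in library 2 is a candidate source. Of 35 blood and liver genes written down before the test, list 2 held 0 further genes beyond these 3, and lists 1 and 3 held 1 each (Hbb-bt and Bpgm), so abundant liver mRNAs such as Apoa1 and Ttr were not listed. Outside these 35 genes, list 1 held sites in the alpha-fetoprotein gene Afp (fold 22.4) and in Albfm1 (9.02), and such sites were therefore not confined to list 2. The lists hold part of the calls, near-identical copies such as Hba-a1 and Hba-a2 can lose their reads, and which of these genes CT26.WT cells express was not known. Reads shared between the haemoglobin copies stay open, and no biological explanation was tested.

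In list 3 the caller's FDR rose with the score (Spearman's rho 0.99 across sites, which are not independent replicates), whereas rho was -0.92 in list 1 and -0.87 in list 2; in all lists the 1% of sites with the highest score had a higher median FDR (19.4, 15.1 and 16.4%) than the other sites (15.5, 13 and 9.72%). In a search over 800 step sizes, made after repeated fold values were seen, 27.8% of the folds in list 1 lay within 0.005 of a multiple of 0.459, 30.7% in list 2 and 19% in list 3 of a multiple of 0.4005, against about 2.18 to 2.5% for a given step by chance; the median fold is 15.7, 16 and 20.9 such steps.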
